A study of Mus musculus with 16 samples.

How the data were processed

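Mouse embryonic stem cells were profiled by MAB-seq, after pulldown of H3K4me1 or H3K27me3 chromatin or on the whole genome, and by BS-seq after pulldown of H3K27me3 chromatin. The 16 samples came as 11 tables with a row per CpG cytosine, and 5 of these tables were pools of 2 samples that the authors had merged. The groups, lines, genotypes, vitamin C doses and hours were taken from the labels. No sample could be separated from its pool, so no replicates exist and no variance between cultures could be estimated.

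Per the submitters' processing notes, reads were handled with Trimmomatic, FastQC, Bismark, Bowtie2 and Picard on genome build mm9, and versions of these tools are not given in the sources used here. The deposited count of T base calls (MAB-seq) or C base calls (BS-seq) at each cytosine was made by the authors from base calls of quality 5 or more, with no scaling. The deposited coverage, a signal column, is the authors' number of C plus T base calls at that cytosine in whole reads, with no scaling. The deposited percent is the authors' T or C base calls divided by that coverage, and on the files it equalled the ratio of the other columns. The authors' description gives an M.SssI error rate of 2.04%, a binomial call at p 0.00025 and an empirical false discovery rate of about 5.1%. The authors' lists of called sites were not used here.

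From these tables the share of T (MAB-seq) or C (BS-seq) reads was computed per library over all reads, over mitochondrial CpGs, and over nuclear cytosines with at least 10 reads in every library of the set. Shares carry 95% Wilson intervals, and differences carry intervals combined from them. A cytosine was called when its T reads exceeded a background rate by a one-sided exact binomial test at p under 0.00025, with its reads thinned to 10 at random (seed 20141). The background rate was the T share of the negative control of the same pulldown over cytosines of under 20% T there, and the H3K4me1 negative control served for the whole genome. Strand symmetry was tested with Fisher's exact test on CpGs with at least 10 reads on both strands. It used calls by the authors' rule, on unthinned reads with their background of 2.04%.

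The 7 planned comparisons were made on T and C reads with Fisher's exact test, two-sided, Benjamini-Hochberg adjusted, with a threshold of 0.05. They were run per cytosine with at least 10 reads in both libraries, and per fixed 1 kb tile with at least 5 covered cytosines and 50 reads in both. In H3K4me1 MAB-seq the Tdg knockdown with vitamin C was compared with the control knockdown, with the negative control and with the Tdg knockdown without vitamin C. In H3K27me3 MAB-seq the Tdg knockdown was compared with the control knockdown and with the Tet1/2 KO. In H3K27me3 BS-seq the Tdg knockdown and the Tet1/2 KO were each compared with the control knockdown. A pair of further tile comparisons, of the Tdg knockdown without vitamin C with the control knockdown and of the control knockdown with the negative control, was added after the data were seen. Reads within a tile are not independent, since a read can cover several CpGs, so p-values over reads are too small.

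The tiles named in the report were the 10 largest rises and 5 largest falls past the threshold with at least 100 reads in both libraries, a rule set before the data were examined. Where a count of calls was 5 or fewer and a call fell outside the rule, it was named after its values were seen. Tiles were grouped by CpG cytosines (under 10, 10 to 39, 40 or more) and by methylation in the control knockdown BS-seq (under 20%, 20 to 80%, over 80%, at least 20 reads), as planned. They were also grouped by whole-genome T share and by pulldown enrichment, chosen after the data were seen. Enrichment was the share of a library's reads in a tile over the share of whole-genome reads there, from the H3K4me1 control knockdown and the BS-seq control knockdown. A tile was enriched from 3 upward, and a tile enriched for neither was below 1 for both marks. Mean differences in BS-seq methylation used tiles with at least 10 reads in both libraries.

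The pipeline was tested on simulated data with the real depths, in which 200 CpGs or tiles per comparison were changed. In the 3 H3K4me1 comparisons the CpG test recovered 0% of rises of 50 points, and with 10 times the reads it recovered 94.0% of rises of 30 points against the control knockdown. In H3K27me3 MAB-seq against the control knockdown it recovered 68.2% of rises of 50 points, and in BS-seq 60.6% for the Tdg knockdown and 40.9% for the Tet1/2 KO. The tile test recovered 56.1% of rises of 20 points in H3K4me1 against the control knockdown, 48.5% against the negative control and 37.9% for vitamin C. It recovered 89.4% in H3K27me3 MAB-seq against the control knockdown, 86.4% against the Tet1/2 KO, and in BS-seq 36.4% for the Tdg knockdown and 34.8% for the Tet1/2 KO. The simulated base was the midpoint of the shares of both libraries over all reads, and falls were not simulated. For the Tdg knockdown in BS-seq those shares were 56.3% and 57.1%, but the tested tiles read 8.62% and 9.71%. The BS-seq tile recoveries therefore do not give the sensitivity at the levels of the tested tiles, or for falls. With T reads clumped in the simulation the false tile calls numbered 4 for H3K4me1 against the control knockdown and 9 for the Tdg knockdown in BS-seq. The binomial call at 10 reads gave 6 false calls among 164095 cytosines and found 16.1% of rises of 20 points and 86.1% of rises of 50 points.

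Depth set what could be seen. The share of covered cytosines with at least 10 reads was 7.08% in the H3K4me1 negative control, 8.46% in the control knockdown, 2.71% in the Tdg knockdown without vitamin C and 6.07% with it. It was 66.3% in the whole-genome library and under 0.1% in every H3K27me3 library, from 0.0277% in the Tet1/2 KO MAB-seq to 0.0842% in the control knockdown BS-seq.

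Alternatives planned before the data were examined were minimums of 5 and 20 reads, unthinned reads, background rates from mitochondrial CpGs or from the authors, calls by Benjamini-Hochberg at 0.05, and leaving out the 194578 cytosines with 20% or more T in a negative control at 5 or more reads. Further planned ones were an adjusted p under 0.01 with a difference of 10 points, strands summed, the deeper library thinned, 500 bp tiles, at least 200 reads per tile, the median tile taken off, and no X or Y chromosome. Alternatives added after the data were seen were all reads of each library, tiles without X and Y, tiles without those 194578 cytosines, and tile p-values widened for overdispersion. The widening used either the spread of the comparison's own tiles, which also holds real differences, or that of the control knockdown against the negative control. Promoters and the gene lists were not analysed here, since no annotation on mm9 was at hand. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Numba 0.67.0 and Matplotlib 3.10.9.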

Results

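Active removal of DNA methylation was measured in mouse embryonic stem cells with methylase-assisted bisulfite sequencing (MAB-seq). In this assay the CpG methyltransferase M.SssI first methylates unmodified CpGs. After bisulfite treatment, 5-formylcytosine (5fC) and 5-carboxylcytosine (5caC) read as T and the other forms of cytosine read as C. The share of T reads at a CpG therefore measures 5fC plus 5caC on top of a background. Bisulfite sequencing without the enzyme (BS-seq) was run on part of the samples, and there the share of C reads measures 5-methylcytosine plus 5-hydroxymethylcytosine. DNA came from chromatin captured with an antibody to H3K4me1, a mark of enhancers, from chromatin captured with an antibody to H3K27me3, a mark of Polycomb repression, or from the whole genome. Tet enzymes make 5fC and 5caC, and the glycosylase Tdg removes them. Tdg was depleted with a short hairpin RNA in the V6.5 line, and vitamin C, a stimulant of Tet enzymes, was given at 100 µg/ml for 60 h or withheld.

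The 16 samples were held in 11 files, of which 5 were pools of 2 samples made by the authors. In H3K4me1 MAB-seq, the control knockdown pooled 1 sample without and 1 with vitamin C, and the Tdg knockdown with vitamin C pooled 2 samples. The Tdg knockdown without vitamin C was 1 sample. The H3K4me1 negative control pooled 1 Dnmt1/3a/3b knockout sample of the J1 line, without vitamin C, and 1 Tet1/2 knockout (KO) sample of the E14Tg2A line, with vitamin C. H3K27me3 MAB-seq, with vitamin C throughout, had 1 control knockdown sample, a pool of 2 Tdg knockdown samples and 1 Tet1/2 KO sample. H3K27me3 BS-seq had 1 sample of each of these groups. The whole-genome library pooled 2 Tdg knockdown samples with vitamin C, 1 of V6.5 at 60 h and 1 of E14Tg2A at 96 h.

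Depth differed widely between libraries. In H3K4me1 MAB-seq, reads over CpG cytosines numbered 80812531 in the negative control, 86882521 in the control knockdown, 45426245 in the Tdg knockdown without vitamin C and 69885914 in the Tdg knockdown with vitamin C. The mean depth per covered cytosine of these 4 libraries was 3.52, 3.61, 2.59 and 3.21 reads. In H3K27me3 MAB-seq, reads numbered 12117617 in the control knockdown, 5865767 in the Tdg knockdown and 12627988 in the Tet1/2 KO, for mean depths of 1.29, 1.13 and 1.28. In H3K27me3 BS-seq they numbered 18615106, 16360615 and 13679322 in the same order, for mean depths of 1.48, 1.41 and 1.35. The whole-genome library held 455722799 reads at a mean depth of 12.2. No group has replicates that the files keep apart, so every test on reads compares libraries and not conditions. Intervals are 95% Wilson intervals, or for differences intervals built from them, and cover counting error only, since PCR reads are not independent molecules.

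The first comparison asks whether 5fC and 5caC build up on H3K4me1 chromatin when Tdg is depleted. The Tdg knockdown with vitamin C carried more T than each of the other 3 H3K4me1 libraries. At the 164095 nuclear CpG cytosines with at least 10 reads in all 4, its T share was 6.07% (6.05 to 6.10). The share was 3.92% (3.89 to 3.94) in the Tdg knockdown without vitamin C, 3.10% (3.08 to 3.12) in the control knockdown and 2.54% (2.53 to 2.56) in the negative control. The Tdg knockdown with vitamin C exceeded the control knockdown by 2.98 percentage points (2.94 to 3.01) and the negative control by 3.53 points (3.50 to 3.57). The control knockdown exceeded the negative control by 0.554 points (0.527 to 0.581). On mitochondrial CpGs the Tdg knockdown with vitamin C and the control knockdown differed by 0.0743 points (-0.336 to 0.501). On the same mitochondrial CpGs the control knockdown exceeded the negative control by 0.707 points (0.299 to 1.10), and their nuclear difference lay inside that interval. With a minimum of 20 reads, which left 2203 cytosines, the Tdg knockdown exceeded the control knockdown by 0.756 points and the negative control itself read 4.47% T.

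**Figure D1:**
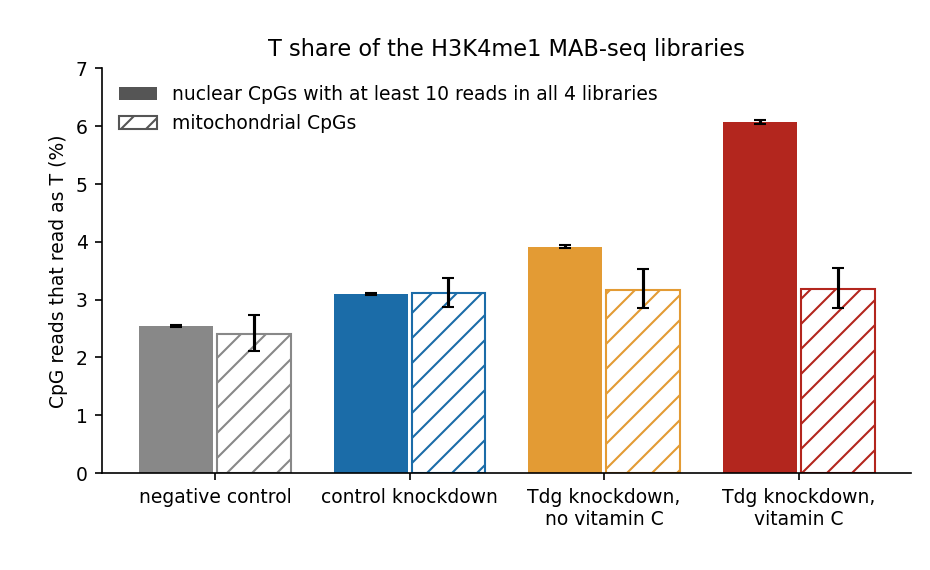
T share in percent (vertical axis) of the 4 H3K4me1 MAB-seq libraries at shared nuclear CpGs and at mitochondrial CpGs, with bars for 95% Wilson intervals. The Tdg knockdown with vitamin C stands at 6.07% on nuclear CpGs and at 3.18% on mitochondrial CpGs, where the control knockdown stands at 3.11%.

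Cytosines with more T than the background allows were counted at 1 depth, with the reads at each cytosine thinned to 10. Of the 164095 shared cytosines, 1336 (0.814%, 0.772 to 0.859) were called in the Tdg knockdown with vitamin C. The count was 305 (0.186%) in the Tdg knockdown without vitamin C, 171 (0.104%) in the control knockdown and 132 (0.0804%) in the negative control. The called share of the Tdg knockdown with vitamin C was 7.81 times that of the control knockdown and 10.1 times that of the negative control. Benjamini-Hochberg calls at 0.05 were adjusted within each library, so the cutoff differed between libraries. They numbered 5649 in the Tdg knockdown with vitamin C, 171 in the control knockdown and 61 in the negative control. The cutoff was thus lower in the Tdg knockdown and higher in the negative control than at p under 0.00025. The ratios of these shares, 33.0 to the control knockdown and 92.6 to the negative control, therefore compare calls at unlike cutoffs. With unthinned reads 3309 were called in the Tdg knockdown with vitamin C. At p under 0.00025, leaving out CpGs of 20% or more T in the negative control raised the ratio to the control knockdown from 7.81 to 15.2. With a minimum of 20 reads the difference from the control knockdown was 0.772 points (-0.199 to 1.76), over 2203 cytosines, and the called share was 1.33 times that of the control knockdown and 1.73 times that of the negative control. In the whole-genome library 87940 of 24872582 cytosines (0.354%) were called, and 0.103% with the T share of its own mitochondrial CpGs as the background. That background, 3.57% (2.71 to 4.71), rests on 1343 reads. At 10 reads the cutoff moves only by whole T reads, and the authors' rate of 2.04% gave the same 87940 calls. The called share was 0.699% with unthinned reads and 0.862% with a minimum of 20 reads.

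In 1 kb tiles, 31386 of 340517 tiles had a higher T share in the Tdg knockdown with vitamin C than in the control knockdown, and 59 a lower one (Fisher's exact test on reads, two-sided, Benjamini-Hochberg adjusted p under 0.05). The median rise was 7.68 points, and 82.2% of all tested tiles leaned upward. The same test between the control knockdown and the negative control, added after the data were seen, passed 4 tiles upward and 8 downward of 357323. With p widened by the spread of tiles between those libraries, a factor of 1.15, the Tdg knockdown was higher in 23628 tiles and lower in 20. With p widened by the spread of the comparison's own tiles, a factor of 1.68 that includes real differences, 616 were higher and 0 lower, with 50968 and 173 at an unadjusted p under 0.05. At single CpGs, 0 of 925929 passed Fisher's exact test with Benjamini-Hochberg adjustment, against 10964 higher and 135 lower at an unadjusted p under 0.05. On simulated data of this depth, with 200 CpGs changed, that test recovered 0% of CpGs raised by 50 points. The adjusted threshold also depends on how many CpGs change, so this holds for changes as sparse as those simulated.

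The files carry no gene names, so tiles are named by coordinate on build mm9. The 10 largest rises over the control knockdown, among tiles of at least 100 reads in both libraries, spanned 19.3 to 28.2 points. The largest lay on chromosome 6 from 94204001 to 94205000, with T in 28.9% of 114 reads (21.4 to 37.9) against 0.794% of 126 reads (0.140 to 4.36), Fisher's exact test with Benjamini-Hochberg adjusted p 3.90e-07. There the whole-genome library read 15.0% T, the Tdg knockdown without vitamin C 14.1% of 64 reads and the negative control 1.16% of 172 reads. The second lay on chromosome 12 from 106958001 to 106959000, with 24.5% of 151 reads against 0.897% of 223 reads, adjusted p 7.72e-09. Both stayed past the threshold with p widened by the comparison's own spread, at adjusted p 0.0111 and 0.00263, and 4 of the 10 did not. Those lay on chromosome 4 from 62054001 (0.0514), chromosome 14 from 55413001 (0.0552), chromosome 18 from 7686001 (0.0915) and chromosome 6 from 89276001 (0.0820). The 5 largest falls spanned -16.0 to -11.6 points, and with that widened p their adjusted p ran from 0.0837 to 0.233. The largest fall, on chromosome 5 from 22940001 to 22941000, had 1.47% of 136 reads against 17.5% of 103 reads in the control knockdown, adjusted p 0.00161, and the negative control read 0.833% there.

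Against the negative control, which lacks either Dnmt1/3a/3b or Tet1/2, the comparison asks where the T of the Tdg knockdown exceeds the background of the assay. In 1 kb tiles, 53196 of 333199 were higher in the Tdg knockdown with vitamin C and 47 lower (Fisher's exact test, Benjamini-Hochberg). With p widened by the spread between the control knockdown and the negative control, 43957 were higher and 22 lower, and by the comparison's own spread 4133 and 1. The 10 largest rises spanned 20.1 to 27.8 points, and all 10 passed with p widened by the comparison's own spread, at adjusted p 0.00187 to 0.0415. The tile on chromosome 7 from 123324001 to 123325000 read 24.6% of 134 reads against 1.86% of 161 reads, adjusted p 1.27e-06. The tile on chromosome 2 from 72361001 to 72362000 read 21.7% of 143 reads against 0 of 139 reads (upper limit 2.69%), adjusted p 4.22e-07. Among the 5 largest falls, the tile on chromosome 15 from 36807001 to 36808000 read 16.4% against 31.7%, and 4.07 points higher in the Tdg knockdown once CpGs of 20% or more T in the negative control were left out. Of 771183 single CpGs 0 were higher and 4 lower, with 8916 higher and 141 lower at an unadjusted p under 0.05. The lower CpGs, named after their values were seen, were chromosome 7 position 125801876, with 0 of 16 reads against 12 of 12, and chromosome X positions 166430229, 166434085 and 166443090.

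The effect of vitamin C was read from the Tdg knockdown with and without it. The T share with vitamin C was 2.16 points higher (2.12 to 2.20) at the 164095 shared cytosines, and 0.355 points higher (0.124 to 0.583) with a minimum of 20 reads. The called share was 4.38 times that without vitamin C. It was 18.5 times with Benjamini-Hochberg calls, whose cutoff was lower in the library with vitamin C than in that without it. With a minimum of 20 reads it was 1.19 times, a difference of 0.499 points with an interval that includes 0. Without vitamin C, the Tdg knockdown exceeded the control knockdown by 0.819 points (0.787 to 0.851), and by 0.401 points with a minimum of 20 reads. In 1 kb tiles 80 of 244041 were higher with vitamin C and 2 lower, against 25517 and 1458 at an unadjusted p under 0.05 (Fisher's exact test, Benjamini-Hochberg). With at least 200 reads per tile 421 of 22749 tiles were higher and 5 lower. With p widened by the spread between the control knockdown and the negative control 1 tile was higher and 1 lower. A comparison of the Tdg knockdown without vitamin C and the control knockdown, added after the data were seen, passed 16 of 252142 tiles upward and 0 downward, with 15027 and 1136 at an unadjusted p under 0.05. At single CpGs 0 of 232110 passed with and without vitamin C, with 757 higher and 233 lower at an unadjusted p under 0.05.

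None of the 10 largest rises with vitamin C passed with p widened by the comparison's own spread, at adjusted p from 0.0661 to 0.529. On chromosome 14 from 21578001 to 21579000 the T share was 22.0% of 214 reads against 2.00% of 100 reads, adjusted p 0.0131 (Fisher's exact test, Benjamini-Hochberg), and 14.4% in the whole-genome library. On chromosome 1 from 51910001 to 51911000 it was 19.9% of 221 reads against 0.667% of 150 reads, adjusted p 0.000126. Of the tiles that were lower, the tile on chromosome 6 from 58546001 to 58547000 read 24.7% against 44.2%, adjusted p 0.0371, with 31.5% T in the control knockdown and 35.1% in the negative control. The other, on chromosome 11 from 54943001 to 54944000 and named after its values were seen, read 15.7% of 83 reads against 64.2% of 53 reads, adjusted p 0.00125.

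The whole-genome Tdg knockdown pool, sequenced without a pulldown, held more T in the tiles that gained T on H3K4me1 chromatin. At 668821 cytosines with at least 10 reads in both and in the negative control, the T share was 6.89% in the whole genome, 6.69% in H3K4me1 chromatin of the Tdg knockdown and 2.36% in the negative control. Tiles that were higher in the H3K4me1 Tdg knockdown than in the control knockdown read 7.90% T (7.89 to 7.92) in the whole-genome library, and tiles not past the threshold 5.90%. Across classes of tiles from 0 to 2% up to 12% or more whole-genome T, the T share of the H3K4me1 Tdg knockdown with vitamin C climbed from 3.09% to 9.80%. In the same classes the Tdg knockdown without vitamin C went from 2.83% to 5.46%, the control knockdown from 2.59% to 3.40% and the negative control from 2.50% to 2.62%. The excess of vitamin C over no vitamin C was 0.255 points in the lowest class and 4.35 points in the highest. These classes, and those by pulldown enrichment, were chosen after the data were seen.

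**Figure D2:**
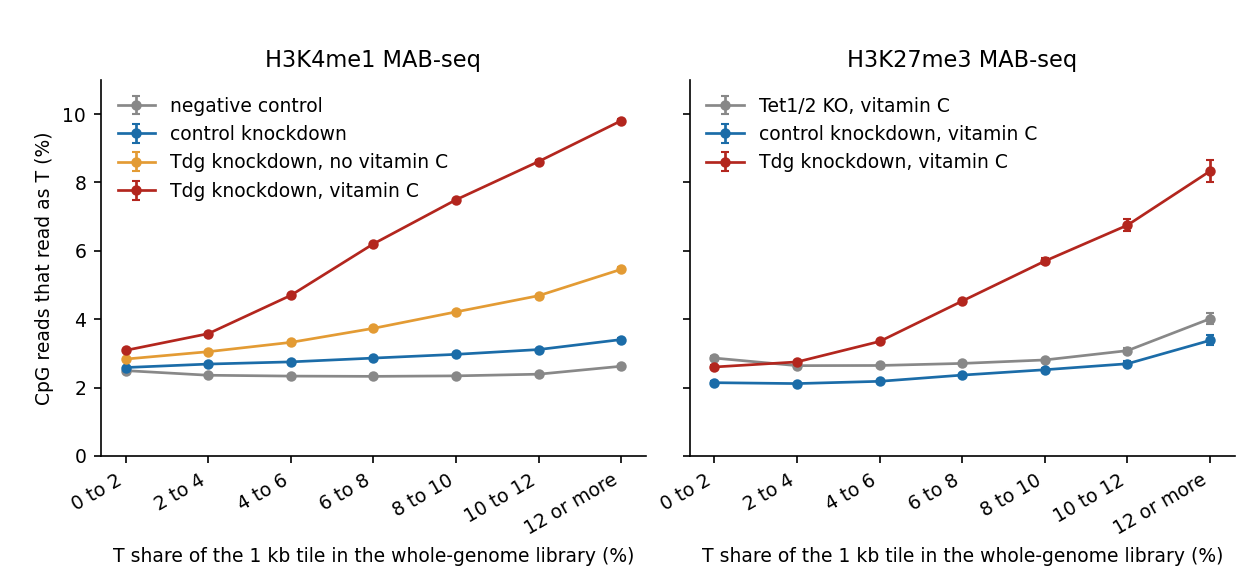
T share in percent (vertical axis) of the 4 H3K4me1 and 3 H3K27me3 MAB-seq libraries in tiles grouped by whole-genome T share (horizontal axis, percent), with bars for 95% Wilson intervals. The Tdg knockdown with vitamin C reaches 9.80% in H3K4me1 chromatin and 8.33% in H3K27me3 chromatin in the class of 12% or more, and the H3K4me1 negative control stays between 2.33% and 2.62%.

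The T share of the Tdg knockdown was highest in tiles enriched for H3K4me1 alone and, in a separate grouping, in tiles of intermediate methylation. Whole-genome T was 6.84% in the 122964 tiles enriched for H3K4me1 alone, 4.96% in the 25687 enriched for H3K27me3 alone, 5.03% in the 10248 enriched for both and 4.14% in the 1305132 enriched for neither. The called share of whole-genome cytosines was 0.865% in tiles enriched for H3K4me1 alone and 0.198% in tiles enriched for neither. Within the H3K4me1 libraries, the Tdg knockdown with vitamin C exceeded the control knockdown by 3.64 points (3.62 to 3.65) in H3K4me1-enriched tiles and by 1.09 points (1.07 to 1.10) in tiles enriched for neither. By methylation in the control knockdown BS-seq, whole-genome T was 4.24% in tiles under 20% methylated, 6.25% in tiles of 20 to 80% and 4.72% in tiles over 80%. By CpG density whole-genome T was 4.02% in tiles of under 10 CpG cytosines, 4.81% in tiles of 10 to 39 and 5.23% in tiles of 40 or more. The H3K4me1 Tdg knockdown with vitamin C did not keep rising over these density classes, at 4.47%, 5.61% and 5.11%, and the negative control went down, at 2.78%, 2.41% and 2.24%. From 10 to 39 to 40 or more cytosines, whole-genome T went from 6.13% to 4.13% among tiles under 20% methylated, from 6.04% to 6.49% among tiles of 20 to 80%, and from 4.57% to 5.00% among tiles over 80%.

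**Figure D3:**
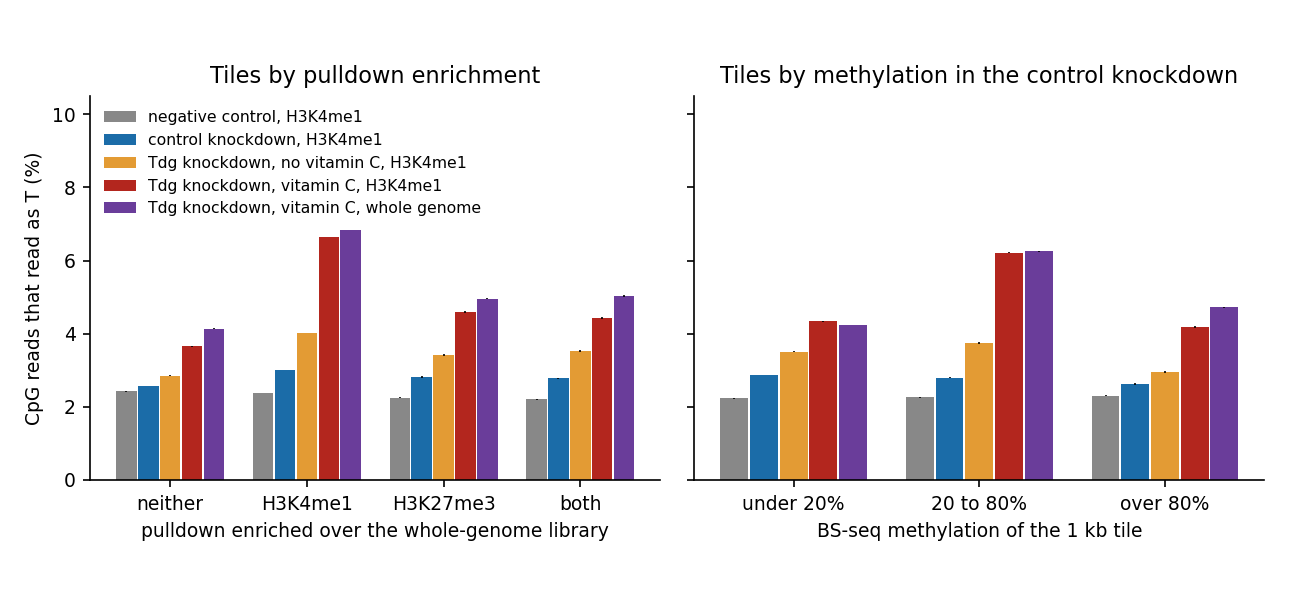
T share in percent (vertical axis) of the 4 H3K4me1 MAB-seq libraries and the whole-genome library, by pulldown enrichment and by BS-seq methylation class of the tile, with bars for 95% Wilson intervals. The whole-genome library stands at 6.84% in tiles enriched for H3K4me1 alone and at 6.25% in tiles of 20 to 80% methylation.

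Most CpGs with a call were called on 1 strand. These calls followed the authors' rule, p under 0.00025 against a background of 2.04%, on unthinned reads. Their sensitivity was not simulated. The call thinned to 10 reads, with the background of the negative control, found 16.1% of simulated rises of 20 points. A missing call on the other strand therefore does not show that T was absent there. In the Tdg knockdown with vitamin C, 407 of 12834 CpGs with a call were called on both strands, 6230 on the plus strand alone and 6197 on the minus strand alone. Of the called cytosines 6.15% (5.75 to 6.57) had a called partner, and calls on the 2 strands were associated with an odds ratio of 2.85 (Fisher's exact test, p 6.67e-68). The odds ratio was larger elsewhere: 268 in the negative control, 48.2 in the control knockdown, 27.1 in the Tdg knockdown without vitamin C and 8.69 in the whole genome. In the whole-genome library 5.47% (5.35 to 5.59) had a called partner, with 3520 of 125220 CpGs called on both strands. In the negative control, where 559 CpGs held a call, the share was 16.4% (13.7 to 19.6). The T share opposite a called cytosine was taken where that partner had at least 10 reads. Called cytosines of 20% or more T in a negative control were left out. It was 10.0% in the Tdg knockdown with vitamin C and 9.45% in the whole genome, against 5.43% and 4.77% over all reads of those libraries. It was 12.8% in the negative control and 7.41% in the control knockdown, against 2.38% and 2.84%. These last 2 values rest on 136 and 1552 called cytosines, against 12833 in the Tdg knockdown with vitamin C. The filter is defined on the negative control itself, where the 136 cytosines read 14.1% T.

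On H3K27me3 chromatin the comparison asks whether 5fC and 5caC also build up where Polycomb repression is marked. Over all reads the T share was 3.56% (3.55 to 3.58) in the Tdg knockdown, 2.27% (2.26 to 2.28) in the control knockdown and 2.78% (2.78 to 2.79) in the Tet1/2 KO. The Tdg knockdown exceeded the control knockdown by 1.29 points (1.27 to 1.31) and the Tet1/2 KO by 0.777 points (0.759 to 0.795). On mitochondrial CpGs the Tet1/2 KO read 3.88% T, and the control knockdown differed from it by -0.897 points (-1.67 to -0.141) and the Tdg knockdown by -0.571 points (-1.45 to 0.339). At the 1101 cytosines with at least 10 reads in all 3 libraries the shares were 9.59%, 6.15% and 7.67%, and the excess over the control knockdown was 3.44 points (3.00 to 3.87). At these few deep cytosines every library, the Tet1/2 KO included, read more T than over all reads. The background rate for calls, from the Tet1/2 KO, was 5.00%. From the lowest to the highest class of whole-genome T, the Tdg knockdown exceeded the control knockdown by 0.459 and by 4.95 points. The Tet1/2 KO exceeded the control knockdown by 0.720 points in the lowest class and by 0.632 points in the highest. Of the 1101 cytosines, 16 were called in the Tdg knockdown, 9 in the control knockdown and 6 in the Tet1/2 KO, and the difference from the control knockdown, 0.636 points (-0.281 to 1.61), had an interval that includes 0. It was 2.45 points (0.756 to 4.20) with unthinned reads and 1.73 points (0.660 to 2.90) with Benjamini-Hochberg calls. Those calls used a lower cutoff in the Tdg knockdown, with 28 calls, than in the control knockdown, with 9. The difference from the Tet1/2 KO was 0.908 points (0.0608 to 1.85), and its interval included 0 under 5 of the 8 alternatives.

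In 1 kb tiles of H3K27me3 MAB-seq, 54 of 6057 were higher in the Tdg knockdown than in the control knockdown and 1 lower (Fisher's exact test, Benjamini-Hochberg), and 23 and 0 with p widened by the comparison's own spread. Against the Tet1/2 KO, 26 of 6009 were higher and 1 lower, and 2 and 0 with p widened in that way. The largest rise over the control knockdown, on chromosome 2 from 163165001 to 163166000, was 16.7% of 138 reads against 2.60% of 385 reads, adjusted p 0.000139. The Tet1/2 KO read 2.63% of 228 reads there, the H3K4me1 Tdg knockdown 2.85% of 772 reads and the whole-genome library 4.58% of 852 reads. Against the Tet1/2 KO the widened adjusted p of this tile was 0.0819, and those of the 10 largest rises ran up to 0.250. The tile on chromosome 11 from 108782001 to 108783000 read 12.8% of 109 reads against 0 of 144 reads (upper limit 2.60%), adjusted p 0.00213 and 0.0542 when widened. The 10 largest rises over the control knockdown spanned 9.22 to 14.1 points. In the whole-genome library the 54 tiles read 4.20% T (4.02 to 4.40) and the tiles not past the threshold 4.07% (4.05 to 4.09). The lower tiles, named after their values were seen, were chromosome 17 from 84585001 to 84586000 against the control knockdown and chromosome 10 from 83996001 to 83997000 against the Tet1/2 KO. At single CpGs 0 of 1280 and 0 of 1172 passed, with 10 higher and 6 lower, and 10 higher and 7 lower, at an unadjusted p under 0.05.

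BS-seq of H3K27me3 chromatin asks whether methylation itself differs in the Tdg knockdown and in the Tet1/2 KO. Over all reads, methylation was lower in the Tdg knockdown and in the Tet1/2 KO than in the control knockdown, though for neither in every class of tiles. It was 57.1% in the control knockdown, 56.3% in the Tdg knockdown and 46.1% in the Tet1/2 KO, and the Tdg knockdown differed by -0.747 points (-0.780 to -0.714). In tiles of 2 to 4% whole-genome T the Tdg knockdown read 51.0% against 50.8%, and in the other classes of whole-genome T it read less than the control knockdown. Mitochondrial CpGs, a measure of C left unconverted, read 1.17% C (0.926 to 1.47) in the control knockdown, 0.181% (0.0955 to 0.345) in the Tdg knockdown and 0.681% (0.471 to 0.982) in the Tet1/2 KO, so the first 2 also differ in this measure. The Tet1/2 KO read 61.1% against 82.3% in the control knockdown in tiles enriched in neither pulldown, 14.4% against 20.2% in tiles enriched for H3K27me3 alone, 39.8% against 36.3% in those for H3K4me1 alone and 8.26% against 7.52% in those for both. At the 2532 cytosines with at least 10 reads in all 3 libraries methylation was 34.5% (34.2 to 34.9), 31.7% (31.4 to 32.0) and 30.1% (29.7 to 30.5) in the control knockdown, Tdg knockdown and Tet1/2 KO, differences of -2.87 points (-3.32 to -2.43) and -4.42 points (-4.92 to -3.92). Over 1 kb tiles of at least 10 reads in both libraries, the mean difference was -2.63 points in 292497 tiles for the Tdg knockdown and -11.4 points in 239301 tiles for the Tet1/2 KO.

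The difference of the Tet1/2 KO from the control knockdown changed sign with whole-genome T. Its mean over tiles was -19.3 points in the class of 0 to 2% whole-genome T, -7.47 points at 6 to 8% and 4.59 points at 12% or more. For the Tdg knockdown the means in the same classes were -2.15, -3.43 and -1.96 points. By pulldown, the Tet1/2 KO mean was -17.3 points in tiles enriched for neither mark and 4.68 points in tiles enriched for H3K4me1 alone. The Tet1/2 KO is of the E14Tg2A line and the control knockdown of the V6.5 line.

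**Figure D4:**
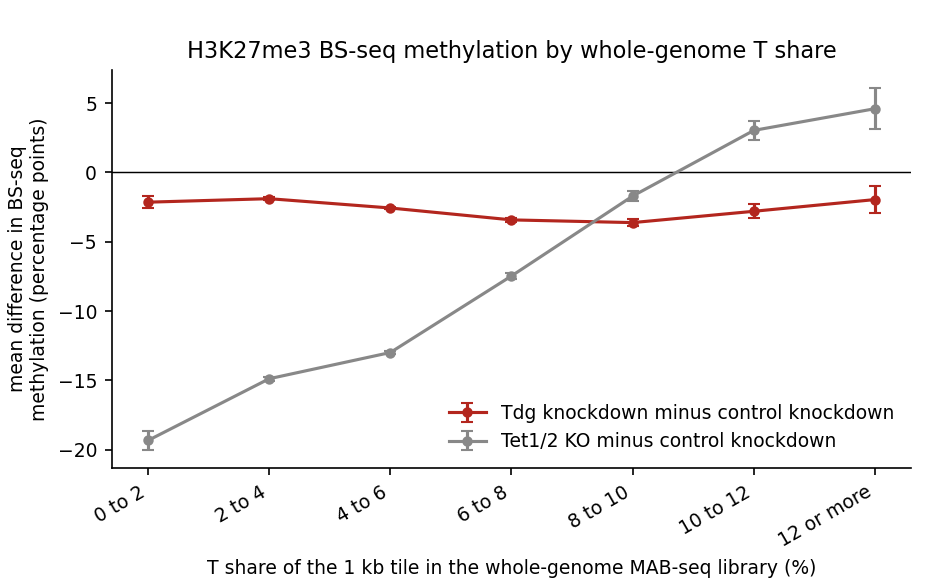
Mean difference in BS-seq methylation from the control knockdown in percentage points (vertical axis), for the Tdg knockdown and the Tet1/2 KO, in tiles grouped by whole-genome T share (horizontal axis, percent), with bars for 95% intervals from the standard error across tiles. The Tet1/2 KO runs from -19.3 points at 0 to 2% to 4.59 points at 12% or more.

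In 1 kb tiles of BS-seq, the Tdg knockdown was higher than the control knockdown in 48 of 22345 and lower in 408, and in 3 and 60 with p widened by the comparison's own spread. The largest fall, on chromosome 9 from 26563001 to 26564000, went from 81.4% of 102 reads in the control knockdown to 35.3% of 136 reads, adjusted p 4.72e-09 (Fisher's exact test, Benjamini-Hochberg), and the Tet1/2 KO read 37.6% of 109 reads there. On chromosome X from 70667001 to 70668000 methylation was 37.0% in the Tdg knockdown, adjusted p 2.50e-07, and 29.6% in the Tet1/2 KO, where it fell by 45.4 points from the control knockdown. Both falls passed in both comparisons with p widened, at adjusted p between 3.42e-05 and 0.0147. The largest rise in the Tdg knockdown, on chromosome 19 from 44836001 to 44837000, was 39.2% of 125 reads against 16.9% of 136 reads, adjusted p 0.0120 and 0.149 when widened, and none of the 10 largest rises passed when widened, at 0.0757 to 0.301. Of 3400 single CpGs 0 were higher and 37 lower, with 29 and 172 at an unadjusted p under 0.05.

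The Tet1/2 KO was higher than the control knockdown in 997 of 19161 tiles and lower in 872, and in 25 and 89 with p widened by its own spread, a factor of 2.52. The largest fall, on chromosome 4 from 118220001 to 118221000, read 28.6% of 182 reads against 79.1% of 700 reads, adjusted p 1.67e-33, with 77.8% in the Tdg knockdown. The largest rise, on chromosome 10 from 42351001 to 42352000, read 53.0% of 100 reads against 21.9% of 224 reads, adjusted p 8.91e-06 and 0.0664 when widened. On chromosome X from 166427001 to 166428000 the Tet1/2 KO read 60.1% of 424 reads against 33.3% of 433 reads, adjusted p 1.28e-12 and 0.000351 when widened. The 10 largest rises spanned 25.2 to 31.1 points, and 4 of them did not pass when widened, at adjusted p from 0.0664 to 0.175. The 5 largest falls spanned -50.6 to -43.5 points. Of 2793 single CpGs 1 was higher and 226 lower (Fisher's exact test, Benjamini-Hochberg). The higher CpG, named after its values were seen, was chromosome 11 position 3093135, with 93.8% of 16 reads against 51.6% of 31 reads, adjusted p 0.0486.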

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

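Of the tests in this part, all 3 on the first pattern, 1 of the 3 on the second (that on whole-genome T), 5 of the 6 on the third, and the comparisons of mitochondrial CpGs and of the rise between pulldowns were chosen after the result was seen. The remaining tests were written before their values were computed, on patterns already seen.

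The rise of T in the Tdg knockdown over the control knockdown had a different size in each pulldown, and which was larger depended on the tiles. Over the 6041 tiles with at least 50 reads in all 4 libraries it was 0.698 points (standard error 0.0227) in H3K4me1 libraries and 0.788 points (standard error 0.0362) in H3K27me3 libraries, a difference of -0.0905 points, although the H3K4me1 rise was the larger in 51.2% of these tiles. Over all reads it was 2.59 points in H3K4me1 and 1.29 points in H3K27me3, and in tiles of 20 to 80% methylation 3.42 and 2.42 points. Tiles are not replicates, so no test of the difference between pulldowns was possible. The H3K4me1 control knockdown pools samples with and without vitamin C while the H3K27me3 one had vitamin C, so the pulldown is not the only difference.

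Mitochondrial CpGs, which the planned comparisons do not use, carried more T in 3 H3K4me1 libraries than in the negative control, at 2.40% (Wilson 2.11 to 2.74). The share was 3.11% in the control knockdown, 3.17% in the Tdg knockdown without vitamin C and 3.18% with it. The Tdg knockdown with vitamin C exceeded the negative control there by 0.781 points (0.320 to 1.24). In H3K27me3 MAB-seq the order was the other way, with 3.88% in the Tet1/2 KO and the control knockdown at -0.897 points from it (-1.67 to -0.141). The cause was not tested.

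The first pattern weighed is the higher T share of the Tdg knockdown with vitamin C over the control knockdown in H3K4me1 libraries. Less complete M.SssI protection would raise T at least as much in unmethylated tiles, but the rise was 1.95 points larger (1.92 to 1.97) in tiles of 20 to 80% methylation than in tiles under 20%. Of the 31830 tiles under 20%, 28694 held 40 or more CpG cytosines, so density also differs. At 10 to 39 cytosines the Tdg knockdown read 6.39% against 3.07% in the control knockdown under 20% methylation. It read 6.37% against 2.84% at 20 to 80%. The rises were close at that density, so there the test does not argue against less complete protection. More conversion of methylated cytosines would raise T most in methylated tiles, but the rise was 1.85 points larger (1.81 to 1.89) in tiles of 20 to 80% than in tiles over 80%. From the lowest to the highest class of T in the separately sequenced whole-genome Tdg knockdown pool the rise grew by 5.90 points (5.82 to 5.98), as 5fC and 5caC left in place by the loss of Tdg would give. That biological reading is a hypothesis, found and tested on the same data, and part of the rise may come from vitamin C, which 1 of the 2 samples in the control knockdown pool did not receive.

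The second pattern is the set of 54 H3K27me3 tiles that were higher in the Tdg knockdown than in the control knockdown. If a few molecules that escaped protection made them, the H3K4me1 libraries should show no extra rise there, and it was 0.300 points (0.00527 to 0.594), between that and the 1 point that would speak against it. The interval counts reads as independent, so one that allowed for clumped reads would be wider and could include no extra rise. Clumping of T on single molecules should make T next to T at least 5 times as frequent as T alone, under 2 times would speak against it, and the ratio was 4.36, against 3.02 in the H3K27me3 control knockdown and 5.04, 4.13 and 4.03 in the H3K4me1 control knockdown, negative control and Tdg knockdown without vitamin C. The ratio was taken over each whole library at cytosines read once, not in the 54 tiles, so it cannot show whether T was clumped in them. 5fC or 5caC of the size seen, a median rise of 11.6 points, in Tdg knockdown DNA at large is argued against by whole-genome T only 0.132 points higher (-0.0564 to 0.329) in these tiles, at 4.20% against 4.07%. Escaped molecules and clumped T cannot be told apart, because both tests fell between their bounds, and 5fC or 5caC held by H3K27me3-marked molecules alone was not tested.

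The third pattern is the lower methylation of the Tet1/2 KO than of the control knockdown in BS-seq over all reads, though not in tested tiles, at 8.34% against 8.28%. Coverage of different CpGs is excluded by a mean difference of -11.4 points (-11.4 to -11.3) over shared tiles and of -11.1 points over the 4430123 cytosines read in both libraries (-4.42 at those with at least 10 reads in all 3 BS-seq libraries), and variants or conversion that read as T in every assay by a MAB-seq T share only 0.323 points (0.305 to 0.342) higher in the Tet1/2 KO. Conversion in the BS-seq reaction alone was not tested there, and a loss in proportion to methylation, the form it would take, is argued against by a difference that was 20.5 points higher (19.4 to 21.5) at 10% or more whole-genome T than at under 4%, among tiles of 20 to 80% methylation in the Tdg knockdown, though control methylation there was 50.9% and 73.9%. Loss of Tet enzymes that otherwise oxidise methylation in T-rich tiles may explain why the difference rose by 23.9 points (22.3 to 25.5) from the lowest to the highest class of whole-genome T. Neither the lower level nor this rise over the classes can be told apart from a difference between lines. Here 0 BS-seq libraries of the E14Tg2A line with Tet1 and Tet2 kept exist. With reads pooled, the Tet1/2 KO read 56.0% in the lowest class and 55.7% in the highest. The V6.5 control knockdown read 78.6% and 51.2%.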

How the results depend on the processing

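Of the results the report rests on, 209 values under an alternative were counts within 1.5 times of the main count, or differences of the same direction whose interval included or excluded 0 as before, whatever their size. A further 65 counts moved by over 1.5 times, 8 differences came to have an interval that includes 0, 3 came to have one that excludes it and 3 changed sign. The alternatives were fixed before the data were examined unless called added, and added ones were chosen after the data were seen. Counts are given as higher then lower, and the cause of a move was not tested.

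With p widened by the spread of each comparison's own tiles (added), H3K4me1 Tdg knockdown tiles numbered 616 and 0 against the control knockdown, 4133 and 1 against the negative control, and 0 and 1 for vitamin C. H3K27me3 MAB-seq tiles numbered 23 and 0 against the control knockdown and 2 and 0 against the Tet1/2 KO. BS-seq tiles numbered 3 and 60 in the Tdg knockdown and 25 and 89 in the Tet1/2 KO. Of 91 named-tile values under this setting 41 stayed past the threshold and 50 did not. With the spread of the control knockdown against the negative control (added), the lower H3K4me1 tiles numbered 20 against the control knockdown and 22 against the negative control, and vitamin C tiles numbered 1 and 1. H3K27me3 MAB-seq then had 0 lower tiles against the control knockdown, and 14 and 0 against the Tet1/2 KO.

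With 500 bp tiles, H3K4me1 counts were 17891 and 39 against the control knockdown, 34389 and 22 against the negative control, and 4 and 1 for vitamin C. H3K27me3 MAB-seq had 2 lower tiles against the control knockdown, and 11 and 0 against the Tet1/2 KO. BS-seq had 16 and 157 in the Tdg knockdown and 589 and 391 in the Tet1/2 KO.

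With at least 200 reads per tile, H3K4me1 counts were 31470 and 17 against the negative control and 421 and 5 for vitamin C, the latter more than the 80 and 2 at 50 reads. H3K27me3 MAB-seq had 2 and 0 against the control knockdown and 0 and 0 against the Tet1/2 KO. BS-seq had 10 and 65 in the Tdg knockdown and 264 and 98 in the Tet1/2 KO. Fewer tiles reach this depth, so these counts are also limited by coverage.

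With the median tile of each library taken off, the number of passing tiles stayed the same and only their direction was read after the shift. By that reading 90 H3K4me1 tiles were lower against the control knockdown and 644 against the negative control. Before the shift the median difference of the 644 was 3.09 points higher in the Tdg knockdown, so they do not count as falls in T share. Without CpGs of 20% or more T in the negative control (added for tiles), lower tiles numbered 19 against the negative control and 1 for vitamin C. This filter removes T from the negative control by construction. It turned the direction of named falls against the negative control at chromosome 15 from 36807001, to 4.07 points higher, and at chromosome 8 from 128882001, to 0.172 points higher. At single CpGs the filter left 0 lower against the negative control and 0 higher in the Tet1/2 KO BS-seq.

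At single CpGs the 4 lower against the negative control became 0 with a minimum of 20 reads, 1 with the deeper library thinned and 1 without the X and Y chromosomes. In the Tdg knockdown BS-seq, the 37 lower CpGs became 12 with a minimum of 5 reads, 20 at an adjusted p under 0.01 and 10 points, and 9 with strands summed. In the Tet1/2 KO BS-seq, the 1 higher and 226 lower became 0 and 76 with a minimum of 5 reads and 0 and 108 at an adjusted p under 0.01 and 10 points. There the lower CpGs numbered 149 with the deeper library thinned, and the higher ones 0 with a minimum of 20 reads and 5 with strands summed.

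The T share of the whole genome minus that of the H3K4me1 Tdg knockdown was 0.199 points on shared cytosines. It was -0.118 points with a minimum of 20 reads, with an interval of -0.259 to 0.0240 that shows no direction, and turned to -0.658 points over all reads of each library (added).

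At a minimum of 20 reads, 4 differences in the called share of H3K4me1 libraries had intervals that include 0 over 2203 cytosines. They were 0.772 points for the Tdg knockdown with vitamin C against the control knockdown, 0.499 against the Tdg knockdown without it, 0.272 for the Tdg knockdown without vitamin C against the control knockdown and 0.545 for the control knockdown against the negative control. As ratios, the first 3 were 1.33, 1.19 and 1.12 times, against 7.81, 4.38 and 1.78 times at a minimum of 10 reads. In H3K27me3 libraries the difference from the control knockdown, 0.636, came to exclude 0 at 2.45 unthinned, 1.73 with Benjamini-Hochberg calls and 1.10 without the X and Y chromosomes. The Benjamini-Hochberg calls used a lower cutoff in the Tdg knockdown than in the control knockdown. The difference from the Tet1/2 KO, 0.908, was 2.91 unthinned. It was 2.00 both with the mitochondrial background rate and with Benjamini-Hochberg calls, where the cutoff was lower in the Tdg knockdown than in the Tet1/2 KO. Its interval came to include 0 at 0.817 with the authors' background rate, 0.697 with a minimum of 20 reads, 0.405 without CpGs of 20% or more T in the negative control and 0.825 without the X and Y chromosomes. With a minimum of 5 reads it was -0.0393, with an interval of -0.480 to 0.398 that shows no direction. Reads were thinned anew without the X and Y chromosomes, over 1091 cytosines against 1101. Calls there numbered 20 in the Tdg knockdown and 11 in the Tet1/2 KO, against 16 and 6 in the main setting. Leaving out cytosines cannot add calls, so the added calls came from the new random draw.

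No paired analysis was possible because the authors pooled exp1 and exp2 in 1 file for each group that had both. Promoters, with their wider and narrower windows, and the 8 gene lists were planned and not run, since no annotation on mm9 was at hand. Depth limits the H3K27me3 counts most, where 6057 tiles were tested against the control knockdown, compared with 340517 in H3K4me1.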

Other observations

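The tile test between the controls, the count by the authors' rule, the look at neighbouring CpGs and the tiles named here were chosen after the data were seen, and no cause was tested.

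Few tiles passed between the control knockdown and the negative control of H3K4me1 MAB-seq, although the control knockdown leaned higher in 60.0% of them, with median tiles of 2.69% and 2.11% T. Fisher's exact test with Benjamini-Hochberg adjustment passed 4 higher and 8 lower tiles of 357323, with 11053 and 2630 at an unadjusted p under 0.05. The higher tiles lay on chromosome 9 from 72511001 (14.6% T of 96 reads against 0 of 146, upper limit 2.56%), chromosome 15 from 31288001 (19.4% of 93 reads against 0 of 116, upper limit 3.21%), chromosome 8 from 111423001 and chromosome 17 from 39982001.

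The tile on chromosome 6 from 58546001 read 44.2% T in the Tdg knockdown without vitamin C, 24.7% with it, 31.5% in the control knockdown and 35.1% in the negative control, but 4.71% in the whole-genome library.

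The largest excess of whole-genome T over the H3K4me1 negative control, among tiles of at least 100 whole-genome reads and 50 in the negative control and the H3K4me1 Tdg knockdown, lay on chromosome 17 from 79399001 to 79400000, with 23.4% of 111 reads. The H3K4me1 libraries there read 10.6% in the Tdg knockdown with vitamin C, 8.33% without it and 2.50% in the control knockdown, with 0 of 66 reads in the negative control.

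Called cytosines in the Tdg knockdown with vitamin C were seldom fully T. By the authors' rule at a minimum of 10 reads, 28725 of 1319912 cytosines (2.18%) were called, and 0.345% of them had 80% T or more. In the negative control 13.1% of the 1639 called cytosines did. The called rate of the negative control was 4.63% of that of the Tdg knockdown, and its called count was 5.71% of that count. The authors give an empirical false discovery rate of 5.1%.

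T on neighbouring CpGs of the same strand came together in every MAB-seq library. Where both were read once, T next to T was 15.3% in the H3K27me3 Tdg knockdown, 12.0% in the H3K4me1 Tdg knockdown with vitamin C, 10.9% in the H3K4me1 negative control and 22.4% in the whole genome. These were 4.36, 3.48, 4.13 and 3.53 times the T share of cytosines read once. The ratio was highest in the H3K4me1 control knockdown, at 5.04, then 4.03 in the Tdg knockdown without vitamin C, 3.02 in the H3K27me3 control knockdown and lowest in the Tet1/2 KO, at 2.89.

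The tiles on chromosome 9 from 26563001 and on chromosome X from 70667001 lost methylation against the control knockdown in both the Tdg knockdown and the Tet1/2 KO. The control knockdown is shared by these comparisons, so an unusual value in it would move both.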
